A study of Mus musculus with 8 samples.

How the data were processed

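The samples were blood monocytes of 12-week-old C57BL/6 mice, sorted into a Gr1hi (Ly6Chi) and a Gr1lo (Ly6Clo) subset. Per the labels, leukocytes from 5 mice were pooled for each sort, and 4 separate sorts gave 4 biological replicates of each subset. Per the labels' protocols, sorted cells went into TRIzol, RNA was isolated with a micro-scale column kit, and in vitro transcription was lengthened from 4 h to 64 h with fresh nucleotides and polymerase added along the way. Long amplification can alter the balance of 3' and 5' signal and the size of measured ratios. The biotin-labelled product was hybridised to Affymetrix genome-wide mouse 3' expression arrays, 1 array per sample. Human monocyte arrays that the series description mentions were not analysed here.

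The deposited values were probe set intensities on a linear scale, from 8.64 to 27145, which the authors had already made comparable between arrays. The submitters' processing notes name GCRMA and MAS5, with no version, role or order, so which of them made these values stays unknown, and the form of normalization was not given in the sources used here. No detection calls were used here. The scale was read from the values themselves: none was negative, and the 8 array medians lay between 80.6 and 83.1. Values were taken to log2 with no pseudocount and no further normalization.

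The table held 45101 probe sets, of which 64 array controls were left out. Gene names came from the platform annotation paired with the table: 34945 probe sets had 1 gene symbol, 932 had several and 9160 are unnamed here. Of the probe sets with 1 symbol, 34741 were matched through the Entrez identifier to a mouse gene table, 204 were not matched and kept the annotation's symbol, and 0 changed name. Probe sets with several symbols are referred to by their family and entered no gene count. No genome positions were used here.

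A probe set was tested if its value lay over the median of the whole table (intensity 81.9, log2 6.36) in at least 4 of the 8 arrays, whatever the subset. This left 22831 probe sets (50.7%), and 22206 were not tested. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, equal array weights, no block), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. Intervals are at 95% and unadjusted. Each gene was represented by the probe set, among its tested ones with 1 symbol, that had the highest mean over all 8 arrays. Of 4848 genes with several tested probe sets, 18 had probe sets called in opposite directions. Where the dimmer subset's mean lay below the table median, the fold was computed against that median and is given as a lower bound.

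The 34 gene lists were written from general knowledge. They covered markers of classical and nonclassical monocytes, chemoattractant receptors, adhesion, scavenging and efferocytosis, PPAR gamma and lipid handling, Toll-like receptors, cytokines, antimicrobial and granule genes, MHC class II, MHC class I, Fc receptors, complement and coagulation, interferon-stimulated genes, transcription factors, survival and apoptosis, cell cycle, lysosome, glycolysis, oxidative phosphorylation, ribosome, migration and cytoskeleton, immediate early and stress genes, neutrophils, T cells, B cells, NK cells, dendritic cells, platelets, red cells, eosinophils and basophils, progenitors, sex-linked transcripts and the panel of sort and subset genes. The 31 lists with at least 5 tested genes, the panel excepted, were tested with limma's camera at its preset correlation of 0.01, adjusted over these lists, and again with an estimated correlation and with fry. Values per array, such as list means, were compared with a two-sided exact permutation test over 70 orders, whose smallest p is 0.0286.

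Genes named were all of the panel, the 12 genes with the largest fold in each direction among those called with no overlap between subsets (provisional symbols left out), in each list the 2 called members with the largest fold in each direction, and in a list with no called member the 2 members with the highest mean. For the migration and cytoskeleton list, the folds of the members this rule names toward Ly6Chi are not reported here. The samples, the test, the filter, the gene rule, the lists, the naming rule and 24 alternative settings were fixed before the data were examined. These settings were a replicate block, leaving out each array, other filters, normalizations, scales, variance models and array weights, other choices of probe set, a threshold of 0.01, other list tests and lists without shared members. Leaving out both samples numbered 1 was chosen after seeing the data, as were gene families by symbol stem.

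The workflow was tested on simulated data of 22831 probe sets with 50 changed at each size. It recovered 12% of changes of 0.25 on the log2 scale, 66% of 0.5, 98% of 1 and 98% of 2, with 5 false calls among 142. The simulated shifted list was called, and of 40 unchanged lists camera called 0. The noise was drawn independently for each probe set, so members of the simulated lists were not correlated. In the data the estimated correlation was 0.26 for interferon-stimulated genes and 0.82 for platelet markers. The simulation therefore does not give the error rate of camera's list calls here. Far fewer probe sets were changed than the 31.1% called in the data, so the recovered shares need not hold there.

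The number of arrays limits the precision. The median within-subset SD was 0.11 and the median half-width of an interval 0.17 on the log2 scale. Correlations between arrays over tested probe sets, which are not independent replicates, ran from 0.989 to 0.993 within a subset and from 0.948 to 0.958 between subsets. The first principal component held 75.7% of the variance and the second 8.41%. The ratio of 3' to 5' signal for beta-actin was 1.30 ± 0.05 in Ly6Chi and 1.24 ± 0.03 in Ly6Clo (SD, n = 4 each, exact permutation p = 0.171), and for GAPDH 1.15 ± 0.11 and 1.09 ± 0.02 (exact permutation p = 0.371). In 6 such array measures the smallest adjusted exact p was 0.729. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.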

Results

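Gene expression was measured in the 2 main subsets of mouse blood monocytes, sorted from 12-week-old C57BL/6 mice by their level of the Gr1 epitope (Ly6C). Ly6Chi cells correspond to the classical monocytes that are known to enter inflamed tissue, and Ly6Clo cells to the nonclassical monocytes that are known to patrol the vessel wall. Each subset had 4 samples, each from a sort of leukocytes pooled from 5 mice, and each sample was hybridised to 1 Affymetrix 3' expression array. The 8 arrays had nearly equal median intensities, from 80.6 to 83.1, and of 45037 probe sets that are not controls 22831 passed the filter on dim signal. Arrays give no read depth, so the number of arrays limits the precision; the median standard error of a difference was 0.08 on the log2 scale. The series sets these subsets beside human monocyte subsets, which were not analysed here, and the single comparison below is Ly6Clo against Ly6Chi. Signed log2 differences are Ly6Clo minus Ly6Chi throughout.

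Ly6Chi monocytes expressed far more of the matrix proteins Vcan and Fn1, the coagulation factor F13a1, the chitinase-like protein Chil3 and the chemokine receptor Ccr2. Ly6Clo monocytes expressed far more of the lipid-handling genes Cd36, Fabp4 and Pparg, the integrin Itgax, the Fc receptor Fcgr4 and the survival gene Bcl2. With camera's preset correlation, the lists of interferon-stimulated, antimicrobial and oxidative phosphorylation genes were called higher in Ly6Chi cells, and those of MHC class II and cell cycle genes higher in Ly6Clo cells. None of these 5 calls held with an estimated correlation (adjusted p = 0.060 to 0.32). Of 11546 genes tested with limma, 3755 were called at a Benjamini-Hochberg adjusted p under 0.05, 1624 of them higher in Ly6Clo and 2131 higher in Ly6Chi. Of these, 448 differed at least 2-fold, 194 higher in Ly6Clo and 254 higher in Ly6Chi. Over all probe sets 7108 were called (31.1%), 3472 higher in Ly6Clo and 3636 higher in Ly6Chi, and the values of the 2 subsets did not overlap for 7266 (31.8%), where chance gives 2.86%. The larger side of the calls turned without Ly6Chi replicate 1 (3486 higher in Ly6Clo and 3275 higher in Ly6Chi) or without Ly6Clo replicate 1 (3203 and 3196). A difference of 4-fold or more was seen for 52 genes higher in Ly6Clo and 44 higher in Ly6Chi.

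Among the genes that define the sort and the subsets, 13 of 20 were called higher in Ly6Clo, 5 higher in Ly6Chi and 2 were not called; adjusted over the list alone 19 were called. Ly6c1, Ly6c2 and Ly6g, genes of the sorted epitope, matched no probe set with a single symbol. Chosen after its value was seen, a probe set annotated jointly to genes of the Ly6c family was 12.8-fold higher in Ly6Chi RNA (log2 difference -3.68, SE 0.09, limma adjusted p = 3.5e-10). Ccr2, the receptor that draws monocytes out of the bone marrow, stood at 12.60 ± 0.08 in Ly6Chi and 10.75 ± 0.21 in Ly6Clo (log2 intensity, mean ± SD, n = 4 each), a 3.59-fold difference. Nr4a1, the nuclear receptor that Ly6Clo monocytes require, was 2.35-fold higher in Ly6Clo (SE 0.08 log2, adjusted p = 3.6e-07). Spn, the sialophorin CD43, was 3.85-fold higher in Ly6Clo, and the integrin chain Itgal (CD11a) 2.26-fold higher. Cx3cr1, the fractalkine receptor used to tell the subsets apart at the protein level, differed by 0.32 (95% interval 0.02 to 0.62, adjusted p = 0.11) and was not called, although the second of its 2 probe sets was. Itgam (CD11b) differed by 0.21 (adjusted p = 0.27) and was not called. The receptor Csf1r differed by 0.19, the smallest called difference of this panel (adjusted p = 0.019).

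**Figure D1:**
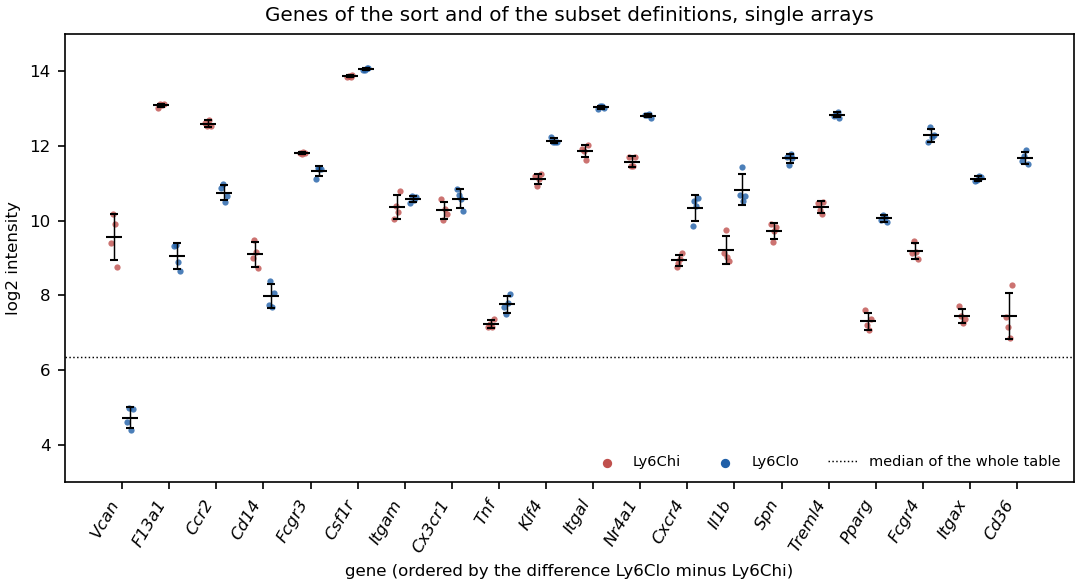
Log2 intensity (vertical axis) of the 20 genes of the sort and the subset definitions (horizontal axis) on each of the 4 Ly6Chi and 4 Ly6Clo arrays; bars are mean and SD, and the dotted line is the median of the whole table. Vcan, F13a1 and Ccr2 were higher on every Ly6Chi array, and Cd36, Itgax, Fcgr4 and Pparg on every Ly6Clo array, while Itgam and Cx3cr1 overlapped.

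Where the dimmer subset lay below the median of the whole table, that median served as a stand-in for background, because no detection calls were used here, and the fold is a lower bound. Vcan, a matrix proteoglycan, was at least 9.25-fold higher in Ly6Chi (log2 difference -4.83, SE 0.25, adjusted p = 9.8e-08). Cd177, a surface glycoprotein best known from neutrophils, was 26.2-fold higher (log2 difference -4.71, SE 0.07, adjusted p = 7.1e-12). Fibronectin (Fn1) was 22.6-fold higher, F13a1 16.3-fold and the collagenase Mmp8 at least 16.5-fold. Chil3 was 11.7-fold higher, the attractin-like gene Atrnl1 stood at 9.82 in Ly6Chi and 6.13 in Ly6Clo, the schlafen family member Slfn4 was 8.60-fold higher, the actin-capping protein Capg 8.46-fold and the receptor tyrosine kinase Met 8.43-fold. Ms4a8a was 7.73-fold higher and the sphingomyelin synthase Sgms2 at least 6.83-fold.

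In the opposite direction, the lymphangiogenic factor Vegfc was at least 7.72-fold higher in Ly6Clo (log2 difference 4.36, SE 0.12, adjusted p = 1.2e-09). Dusp16, a MAP kinase phosphatase, was 19.6-fold higher, the fatty acid binding protein Fabp4 19.0-fold and the scavenger receptor Cd36 18.9-fold. The ion cotransporter Slc12a2 was 17.8-fold higher, Itgax (CD11c) 12.7-fold, the transglutaminase Tgm2 12.5-fold and the enolase isoform Eno3 11.1-fold. Cd83 was 9.79-fold higher, Tgfbr3 9.68-fold, the lymphoid transcription factor Ikzf3 at least 8.83-fold and G0s2, an inhibitor of triglyceride lipase, 8.78-fold.

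**Figure D2:**
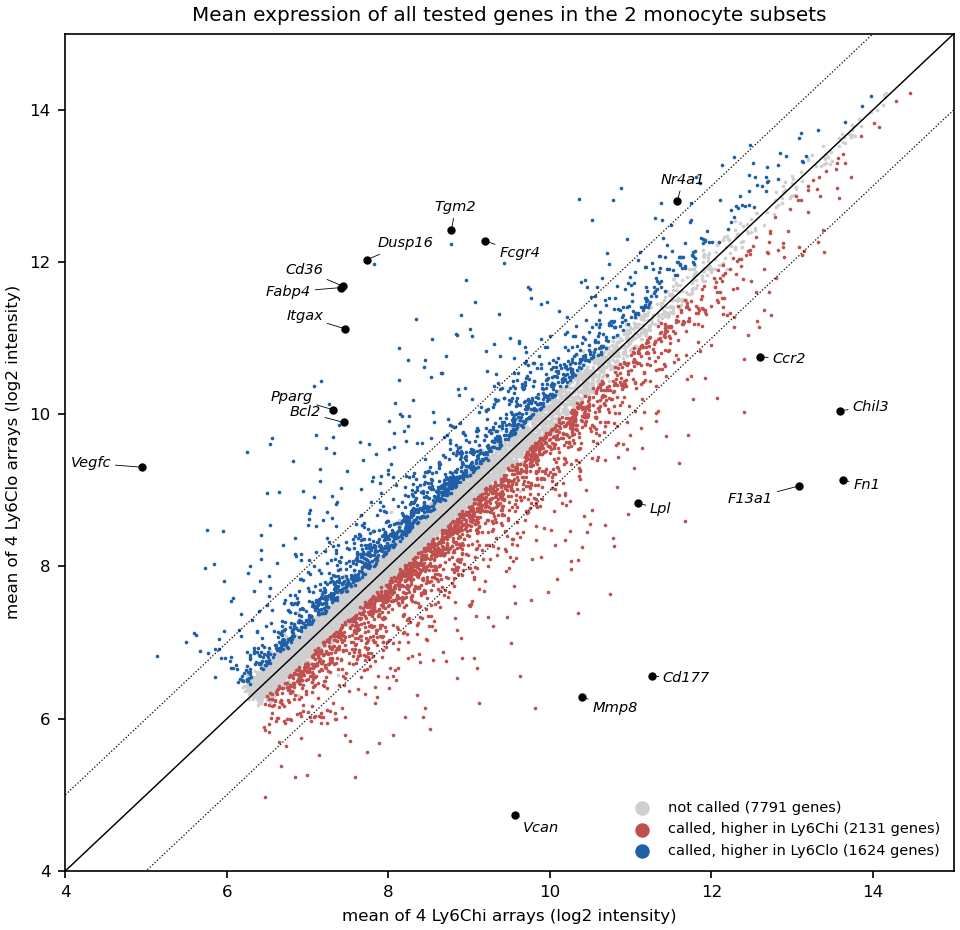
Mean log2 intensity of the 4 Ly6Chi arrays (horizontal axis) and of the 4 Ly6Clo arrays (vertical axis) for each of the 11546 tested genes; the solid line marks equality and the dotted lines a 2-fold difference. The 1624 genes called higher in Ly6Clo lie above the solid line and the 2131 called higher in Ly6Chi below it.

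Of 11 measured markers known for classical monocytes, 10 were called higher in Ly6Chi and none higher in Ly6Clo (10 adjusted over the list alone). Vcan, Cd177 and Fn1 led it, and the list was called by camera (adjusted p = 1.2e-12; adjusted p = 0.039 with an estimated correlation). Of 19 measured markers known for nonclassical monocytes, 18 were called higher in Ly6Clo, and 19 adjusted over the list alone. Treml4, a receptor of the TREM family, was 5.52-fold higher and the peptidoglycan receptor Pglyrp1 5.05-fold higher, and the list was called (adjusted p = 8.1e-22; adjusted p = 0.039 with an estimated correlation). Both lists came from general knowledge to which profiles of these same subsets contributed, so their direction is not independent evidence.

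Genes of PPAR gamma and lipid handling moved in both directions, with 11 of 30 called higher in Ly6Clo and 7 higher in Ly6Chi (18 adjusted over the list alone). Pparg, the nuclear receptor that drives fatty acid uptake and storage genes, was 6.72-fold higher in Ly6Clo (SE 0.10 log2, adjusted p = 7.1e-09). Fabp4 and Cd36, both known PPAR gamma targets, were the leading members. Lipoprotein lipase, Lpl, was 4.76-fold higher in Ly6Chi and the PPAR partner Rxra 1.67-fold higher. The list as a whole was not called by camera (adjusted p = 0.27). Scavenging and efferocytosis genes were likewise divided, with 8 of 23 higher in Ly6Clo and 7 higher in Ly6Chi (9 and 7 adjusted over the list alone; camera adjusted p = 0.48). Tgm2 and the complement component C1qa (at least 3.15-fold) were higher in Ly6Clo, while Cd93 was 4.03-fold and the scavenger receptor Msr1 2.50-fold higher in Ly6Chi.

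Of 16 genes of MHC class II antigen presentation, which include Cd83, Cd40 and Ifi30 beside class II genes, 8 were higher in Ly6Clo and 3 higher in Ly6Chi. The counts were the same adjusted over the list alone. The list was called by camera (adjusted p = 0.022, and adjusted p = 0.32 with an estimated correlation). H2-Eb1 was 4.08-fold and H2-Aa 2.14-fold higher in Ly6Clo, beside Cd83. The thiol reductase Ifi30 was 2.14-fold and the costimulatory receptor Cd40 1.53-fold higher in Ly6Chi. The call was lost when members shared with the dendritic cell list were left out (adjusted p = 0.078) and when probe sets that can match several transcripts were left out (adjusted p = 0.053), in a range of 0.0051 to 0.32 over all camera settings. Of 13 MHC class I genes, 4 were called (30.8%, against 31.1% of all tested probe sets). All 4 were higher in Ly6Clo (4 adjusted over the list alone, camera adjusted p = 0.27), led by H2-K1 at 1.51-fold and H2-D1 at 1.34-fold. Both H2-K1 and H2-D1 are represented by probe sets that can match several transcripts, so their folds may not be specific to these genes. Chosen after their values were seen, 3 probe sets annotated jointly to class I genes of the H2-Q family were 4.03-fold, at least 4.05-fold and 5.20-fold higher in Ly6Clo. The list of Fc receptors and their signalling genes had 6 of 12 higher in Ly6Clo and 4 higher in Ly6Chi (11 adjusted over the list alone, camera adjusted p = 0.47). Fcgr4, a receptor for IgG2 complexes, was 8.52-fold and the neonatal receptor Fcgrt 1.71-fold higher in Ly6Clo. The high-affinity receptor Fcgr1 was 2.34-fold, the inhibitory receptor Pirb 1.91-fold and Fcgr3 1.39-fold higher in Ly6Chi.

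Type I interferon response genes were higher in Ly6Chi as a group. Of 28 measured members, 24 were called higher in Ly6Chi and none higher in Ly6Clo (27 adjusted over the list alone), and the list was called (adjusted p = 1.0e-14; adjusted p = 0.092 with an estimated correlation). Ifit2, an inhibitor of viral translation, was 4.22-fold higher and the ISG15 protease Usp18 4.13-fold higher. Cytokine and chemokine genes had 9 of 27 higher in Ly6Chi and 3 higher in Ly6Clo (12 adjusted over the list alone; camera adjusted p = 0.17). With members shared with cell type lists left out, camera called the list higher in Ly6Chi (adjusted p = 0.029; 0.029 to 0.39 over all camera settings). The interferon-induced chemokine Cxcl10 was 4.80-fold higher in Ly6Chi and Tnfsf14 at least 1.89-fold. Il1b was 3.08-fold higher in Ly6Clo, the growth factor Pdgfb 3.06-fold and Tnf 1.44-fold. Toll-like receptors and their adaptors had 8 of 22 higher in Ly6Chi and 4 higher in Ly6Clo (12 adjusted over the list alone; camera adjusted p = 0.30). The co-receptor Cd14 was 2.17-fold and Ly86 1.61-fold higher in Ly6Chi, while the nucleic acid receptors Tlr7 and Tlr13 were 1.45-fold and 1.35-fold higher in Ly6Clo.

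Antimicrobial and granule genes were higher in Ly6Chi for 13 of 22 members and higher in Ly6Clo for 1, Pglyrp1 (15 adjusted over the list alone). The list was called (adjusted p = 5.4e-05; adjusted p = 0.060 with an estimated correlation), led by Mmp8, Chil3 and the serine protease Prtn3 (at least 4.47-fold). Neutrophil markers, a check for another Gr1-bearing cell, had 7 of 12 higher in Ly6Chi and 1 higher in Ly6Clo (9 adjusted over the list alone), and this list was called too (adjusted p = 2.6e-04; adjusted p = 0.054 with an estimated correlation). Cd177 and Mmp8 led it. Chosen after their values were seen, S100a9, Ngp, Camp and Ltf, all abundant in neutrophil lineage cells, differed by -0.79, -0.42, -0.31 and -0.21 and were not called. S100a8, chosen likewise, was called higher in Ly6Chi (log2 difference -1.82), and the inflammatory receptor Trem1 was 3.95-fold higher in Ly6Clo. Complement and coagulation genes had 6 of 17 higher in each subset (12 adjusted over the list alone; camera adjusted p = 0.66). Beside F13a1, the coagulation factor F5 was 4.32-fold higher in Ly6Chi, and C1qc was at least 2.34-fold higher in Ly6Clo.

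Receptors for chemoattractants had 5 of 16 higher in Ly6Clo and 3 higher in Ly6Chi (9 adjusted over the list alone; camera adjusted p = 0.66). Ccr1 was 4.97-fold higher in Ly6Chi, like Ccr2, while the sphingosine phosphate receptor S1pr5 was 7.48-fold and Cxcr4 2.64-fold higher in Ly6Clo. Adhesion genes were higher in Ly6Clo for 12 of 24 and higher in Ly6Chi for 5 (18 adjusted over the list alone), and the list was called (adjusted p = 0.0024; adjusted p = 0.17 with an estimated correlation). Itgax led it, with Pecam1 at least 2.94-fold higher in Ly6Clo. The collagen receptor chain Itga1 was at least 2.16-fold and Ninj1 2.45-fold higher in Ly6Chi. Of 31 migration and cytoskeleton genes, 10 were higher in Ly6Clo and 4 higher in Ly6Chi (15 adjusted over the list alone), none of them by 2-fold. This list was called (adjusted p = 0.022; adjusted p = 0.51 with an estimated correlation), with the myosin Myo1g 1.99-fold and the actin regulator Vasp 1.86-fold higher in Ly6Clo.

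Transcription factors of the monocyte lineage had 10 of 31 higher in Ly6Clo and 9 higher in Ly6Chi (19 adjusted over the list alone; camera adjusted p = 0.36). Tcf7l2 (at least 4.31-fold), Bhlhe40 (5.55-fold) and Klf4 (2.02-fold) were higher in Ly6Clo, and Maf (2.80-fold) and the myeloid factor Cebpa (2.43-fold) were higher in Ly6Chi. Survival and apoptosis genes had 4 of 19 higher in Ly6Clo and 6 higher in Ly6Chi (10 adjusted over the list alone; camera adjusted p = 0.98). The antiapoptotic gene Bcl2 was 5.45-fold higher in Ly6Clo (SE 0.21 log2, adjusted p = 4.2e-06), while the proapoptotic Bcl2l11 was 2.00-fold and the death receptor Fas 1.67-fold higher in Ly6Chi. The proapoptotic Pmaip1 was 1.85-fold higher in Ly6Clo. A probe set annotated jointly to the Bcl2a1 family, chosen after its value was seen, was 8.49-fold higher in Ly6Clo. Cell cycle genes had 9 of 22 higher in Ly6Clo and 2 higher in Ly6Chi (12 adjusted over the list alone), and the list was called (adjusted p = 0.0015; adjusted p = 0.075 with an estimated correlation). Toward Ly6Clo the helicase subunits Mcm5, at 2.56-fold, and Mcm6, at 2.36-fold, led the list. Named after their values were seen, Mcm2, Mcm3, Mcm4 and Mcm7 were also among these 9, so most of the 9 were Mcm genes. The mitotic kinase Aurkb and the proliferation marker Mki67 were at least 1.75-fold and at least 1.32-fold higher in Ly6Chi.

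Nuclear genes of oxidative phosphorylation were higher in Ly6Chi for 21 of 33 members and higher in Ly6Clo for none (24 adjusted over the list alone). All of these differences were under 2-fold, with the complex I subunit Ndufb5 at 1.54-fold and the ATP synthase subunit Atp5c1 at 1.48-fold, and the list was called (adjusted p = 1.2e-05; adjusted p = 0.21 with an estimated correlation). Lysosomal genes had 13 of 25 higher in Ly6Chi and 3 higher in Ly6Clo (17 adjusted over the list alone), and were called (adjusted p = 0.0047; adjusted p = 0.17 with an estimated correlation). The cholesterol-binding protein Npc2 was 1.95-fold and the protease Ctsc 1.79-fold higher in Ly6Chi, while Ctsb and Lgmn were 1.49-fold and 1.45-fold higher in Ly6Clo. Glycolysis genes had 9 of 22 higher in Ly6Clo and 6 higher in Ly6Chi (15 adjusted over the list alone; camera adjusted p = 0.39). Beside Eno3, the lactate exporter Slc16a3 was 1.69-fold higher in Ly6Clo, and Ldhb was 1.64-fold and Hk1 1.33-fold higher in Ly6Chi. Ribosomal protein genes had 7 of 23 higher in Ly6Chi and 1 higher in Ly6Clo (8 adjusted over the list alone; camera adjusted p = 0.18), among them Rpl37 at 1.36-fold and Rpl14 at least 1.39-fold toward Ly6Chi and Rps25 at 1.55-fold toward Ly6Clo. With the average of each gene's probe sets, camera called the ribosomal list higher in Ly6Chi (adjusted p = 0.033; 0.033 to 0.69 over all camera settings).

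**Figure D3:**
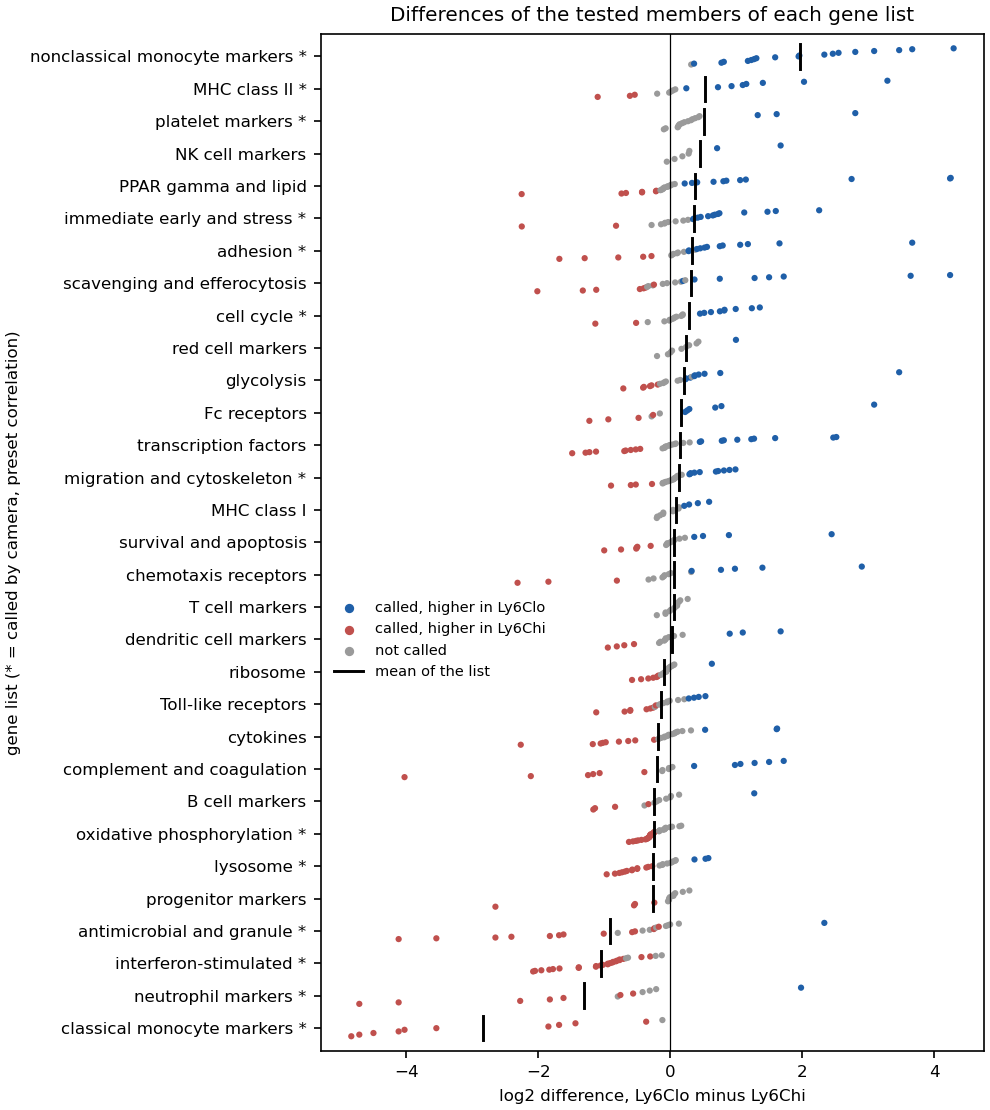
Log2 difference, Ly6Clo minus Ly6Chi (horizontal axis), of each tested member of the 31 gene lists tested (vertical axis); points are genes coloured by their call, black bars are list means, and asterisks mark lists called by camera with the preset correlation. The nonclassical markers lie right of 0 with a mean of 1.97, and the classical markers left of it with a mean of -2.83.

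Immediate early and stress genes, which handling and sorting are known to induce, had 13 of 23 higher in Ly6Clo and 2 higher in Ly6Chi (15 adjusted over the list alone). The list was called (adjusted p = 0.0030; adjusted p = 0.17 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, was 4.78-fold and Jun 3.03-fold higher in Ly6Clo. Fos was 4.75-fold and Atf3 1.77-fold higher in Ly6Chi.

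Markers of other blood cells were measured to see what the sorted samples could hold besides monocytes. Platelet markers had 3 of 17 higher in Ly6Clo and 14 not called (3 adjusted over the list alone); the 3 were Cd9 (6.99-fold), Pdgfb and, named after its value was seen, Vwf (log2 difference 1.33). Their list was called (adjusted p = 0.022; adjusted p = 0.69 with an estimated correlation), and the call was lost without Ly6Chi replicate 4 (adjusted p = 0.078) or without Ly6Clo replicate 1 (adjusted p = 0.16), in a range of 4.6e-04 to 0.69 over all camera settings. Red cell markers had 1 of 10 called, the transferrin receptor Tfrc, 2.00-fold higher in Ly6Clo (1 adjusted over the list alone; camera adjusted p = 0.40). NK cell markers had 2 of 7 higher in Ly6Clo, Klrd1 at 3.19-fold and Gzma at 1.64-fold (2 adjusted over the list alone), with a camera adjusted p = 0.053 that was 0.015 without Ly6Chi replicate 1, 0.037 without Ly6Clo replicate 2 and 0.029 without Ly6Clo replicate 3, in a range of 0.010 to 0.53 over all camera settings. B cell markers had 4 of 13 higher in Ly6Chi, led by Fcmr (at least 1.78-fold) and Ms4a1 (at least 1.85-fold). Toward Ly6Clo 1 was called, the inhibitory lectin Cd22 at 2.42-fold (5 adjusted over the list alone, camera adjusted p = 0.40). Chosen after its value was seen, a probe set annotated jointly to immunoglobulin kappa genes was 4.37-fold higher in Ly6Chi. Its log2 difference was -2.13 (limma adjusted p = 0.0077), with SDs of 0.44 in Ly6Chi and 1.33 in Ly6Clo. It entered no list. Of 13 T cell markers limma called none, adjusted over all probe sets or over the list alone, and 1 had an unadjusted p under 0.05; the signalling kinase Zap70 differed by 0.06 and Cd3d by 0.15 (camera adjusted p = 0.40). Dendritic cell markers had 3 of 15 higher in Ly6Clo, 2 of them at least 2-fold (Klrd1 and H2-Aa). Another 4 were higher in Ly6Chi, among them Bst2 at 1.92-fold and Kmo at 1.75-fold (7 adjusted over the list alone, camera adjusted p = 0.77). Progenitor markers had 4 of 13 higher in Ly6Chi (4 adjusted over the list alone, camera adjusted p = 0.44). They included Prtn3, named above and the 1 member at least 2-fold higher, and Flt3 at 1.46-fold. Only 2 eosinophil and basophil markers passed the filter and neither was called (0 adjusted over the list alone), with differences of 0.08 for Gata2 and -0.01 for Hdc. Of 4 sex-linked transcripts 1 was called, Eif2s3y, with a difference of -0.20 (1 adjusted over the list alone).

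In 7 of the 9 lists of other cell types, the sample numbered 1 held the highest mean in both subsets. For platelet markers it stood at 8.54 in Ly6Chi, against 7.60 to 7.94 for the others, and at 8.97 in Ly6Clo, against 8.08 to 8.54. Neutrophil markers stood at 8.32 in Ly6Chi replicate 1, against 7.96 to 8.01. Without both samples numbered 1, a choice made after seeing these values, 3159 genes were called, 1469 higher in Ly6Clo and 1690 higher in Ly6Chi. The interferon-stimulated list then had 23 genes higher in Ly6Chi, oxidative phosphorylation 17, the classical list 10, antimicrobial and granule genes 14, and the nonclassical list had 18 and the cell cycle list 9 higher in Ly6Clo. The genes higher in Ly6Chi fell to 4 in the PPAR gamma and lipid list and to 4 among ribosomal protein genes, from 7 in each, and Eif2s3y lost its call (adjusted p = 0.12).

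**Figure D4:**
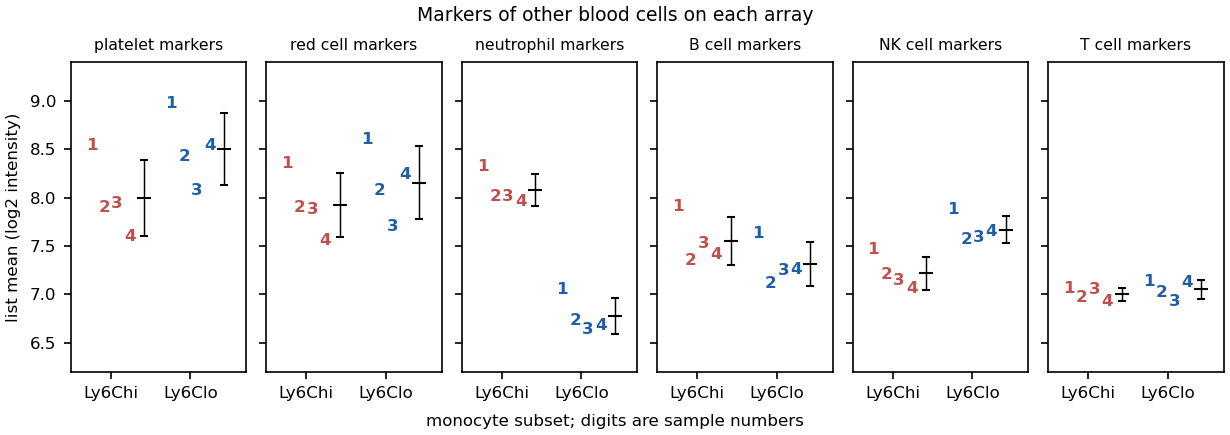
Mean log2 intensity (vertical axis) of the tested markers of 6 other blood cell types in each sample of the 2 subsets (horizontal axis); digits are the sample numbers 1 to 4, and bars are mean and SD of the 4 samples. The samples numbered 1 stand highest for platelet and red cell markers in both subsets.

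Of the 31 lists, 13 were called by camera with its preset correlation, 7 higher in Ly6Clo and 6 higher in Ly6Chi, and only the classical and nonclassical markers held with an estimated correlation. Members called made up 30.8% of the MHC class I, 34.8% of the ribosomal, 38.5% of the B cell, 28.6% of the NK cell and 30.8% of the progenitor list. Of all tested probe sets 31.1% were called, so these counts alone do not set those lists apart. List mean, median and test direction differed in sign for 6 lists. For the chemoattractant receptor, scavenging, lipid and transcription factor lists the medians were -0.05, -0.05, -0.02 and -0.01 and the means above 0. For the survival and dendritic cell lists camera pointed toward Ly6Chi with means of 0.05 and 0.02. Csf1r lost its call without Ly6Clo replicate 3 (adjusted p = 0.052) or Ly6Clo replicate 4 (adjusted p = 0.054; 1.5e-04 to 0.056 over all settings), and Eif2s3y without any single array except Ly6Chi replicate 3 (adjusted p = 0.052 to 0.10; 0.021 to 0.12 over all settings). Cx3cr1 gained a call with the average of its probe sets (difference 0.37, adjusted p = 0.029) and without Ly6Chi replicate 1 (adjusted p = 0.034) or Ly6Clo replicate 4 (adjusted p = 0.026; 0.026 to 0.27 over all settings), and Itgam without Ly6Chi replicate 4 (adjusted p = 0.015; 0.015 to 0.58 over all settings).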

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

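The tests of neutrophil carry-over given here were chosen after the results were seen. Of 316 groups of 4 values examined, 25 held a sample far from the other 3 by Dixon's criterion, where chance gives about 15.8 (1 in 20), and 8 of the 25 concerned a sample numbered 1. Values are log2 intensities unless stated.

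In the Ly6Chi samples, F13a1 stood at 13.004 in replicate 1, below 13.10 to 13.12 in the others, and Arhgef6 at 10.75, above 10.48 to 10.50. Mcm5 stood at 7.86 in replicate 2, above 7.59 to 7.60. H2-Eb1 stood at 10.49 in replicate 4, below 10.86 to 10.91, and Gzma at 7.13, below 7.61 to 7.67. Among list means, replicate 1 was highest for MHC class II genes (9.61), glycolysis genes (9.35) and neutrophil markers (8.32). Replicate 3 was lowest for MHC class I genes (10.90) and the panel of sort and subset genes (10.04), and replicate 4 was lowest for chemoattractant receptors (8.37). The Dap labelling control had an intensity of 1178 in replicate 3, above 570 to 659.

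In the Ly6Clo samples, replicate 1 was lowest for Fcgr3 (11.12) and Cd177 (6.49) and highest for Klf4 (12.23). Replicate 2 was highest for Atrnl1 (6.597, against 5.92 to 6.03), Met (6.89) and Usp18 (7.85), and lowest for G0s2 (9.41) and Hdc (7.02). Replicate 3 was highest for Slc12a2 (12.22) and lowest for Atp5c1 (11.39) and for the means of adhesion genes (9.82) and cytokines (7.90). Replicate 4 was lowest for the mean of nonclassical markers (11.64).

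Neutrophils also carry the Gr1 epitope, and 7 of 12 of their markers were called higher in Ly6Chi. Cells carried over would bring their abundant transcripts along. The mean difference of S100a8, S100a9, Ngp, Camp and Ltf was -0.71 (95% interval -1.50 to 0.07, exact permutation p = 0.114), while the smallest difference among Cd177, Mmp8 and Padi4 was -2.27. The interval lies short of that value, but these 5 genes lay near the table median, so the comparison does not exclude neutrophils as a source of the 3 genes. For S100a8 alone, at -1.82, the mean of S100a9, Ngp, Camp and Ltf was -0.43 (95% interval -1.07 to 0.20, exact permutation p = 0.143). Carry-over and expression by Ly6Chi monocytes cannot be told apart for any of these genes, because the transcripts that would show carry-over lay near the table median, and S100a8 and S100a9 varied widely between replicates.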

How the results depend on the processing

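Of 25 settings besides the reported one, 1 was chosen after the results were seen: leaving out both samples numbered 1. No named gene or list that was called reversed its direction. The larger side of the probe sets called turned toward Ly6Clo without Ly6Chi replicate 1, without Ly6Clo replicate 1 and without both (3150 higher in Ly6Clo and 2844 higher in Ly6Chi). Of 119 named genes 113 were called, all 113 kept their direction in every setting, and 110 kept their call in every setting. Of the 6 not called, 2 changed sign.

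Leaving out each array in turn gave 6229 to 6761 probe sets called, 791 to 825 called and at least 2-fold, 3309 to 3526 genes and 12 to 14 gene lists. With a threshold of 0.01, 2290 probe sets were called higher in Ly6Clo, because the threshold is stricter. With an estimated correlation camera called 2 lists, and fry, which does not compare a list with other genes, called 23. Quantile normalization gave 7471 probe sets and median centring 6796. A pseudocount of 32, which shrinks folds of dim probe sets, gave 644 called and at least 2-fold.

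Residual correlations did not show that the sample numbers pair the samples. Between samples of the same number they were 0.27, 0.34, -0.03 and -0.10. The highest of any pair, 0.55, joined Ly6Chi replicate 4 to Ly6Clo replicate 3. A pairing is not excluded either. Per the labels, 4 separate sorts gave the 4 replicates of each subset, so samples of the same number could share a sort. In 7 of the 9 lists of other cell types, the sample numbered 1 held the highest mean in both subsets. A replicate block gave 7164 probe sets called, 3547 higher in Ly6Clo, and 6730 of the 7108 calls remained. With it Cx3cr1 (adjusted p = 0.028) and the NK cell list (0.023) gained a call and Eif2s3y (0.070) lost its call. Without both samples numbered 1, 5994 probe sets were called, and 5731 of the 7108 remained. Signal near the table median limits folds, which are lower bounds there.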

Other observations

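The tests of families, platelets, handling and other splits of the samples were all chosen after the results were seen. Gene families grouped by symbol stem gave a further view of the 2 subsets. All 7 tested annexins, which bind membranes in the presence of calcium, were called higher in Ly6Chi, with log2 differences of -2.31 for Anxa3, -1.06 for Anxa4 and -1.01 for Anxa1 (camera adjusted p = 1.6e-04; adjusted p = 0.49 with an estimated correlation). All 6 tested schlafens, known interferon-inducible regulators of growth and of viral translation, were higher in Ly6Chi, with -3.10 for Slfn4, -2.29 for Slfn1 and -1.78 for Slfn5 (camera adjusted p = 3.9e-04; adjusted p = 0.997 with an estimated correlation). Of 6 galectin symbols 5 were higher in Ly6Chi, led by Lgals9 at -1.75 and Lgals1 at -1.44. Of 11 intraflagellar transport genes 8 were higher in Ly6Chi, among them Ift57 at -0.89 and Ift172 at -0.47.

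Of 19 nucleoporin symbols 13 were higher in Ly6Clo and 1 higher in Ly6Chi, led by Nup210 at 1.05 and Nup107 at 0.90. Of 7 Smc genes, which encode the ATPases of cohesin, condensin and the Smc5/6 complex, 4 were higher in Ly6Clo, with 2.18 for Smc6 and 1.42 for Smc2. Of 9 Mcm symbols 6 and of 8 augmin subunits (Haus) 5 were higher in Ly6Clo. The 6 Mcm genes, Mcm2 to Mcm7, are also members of the cell cycle list, so they add no separate evidence to it. Of 338 families camera called 14 with the preset correlation and 0 with an estimated correlation, where 9 had an unadjusted p under 0.05.

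Cd9, Vwf and Pdgfb were the platelet markers called higher in Ly6Clo, and platelets can adhere to monocytes. The mean difference of the other 14 platelet markers was 0.21 (95% interval -0.49 to 0.91, exact permutation p = 0.514). With the mean of these 14 markers as a covariate the smallest difference of the 3 was 1.13. The 14 markers are those of the list that were not called, so neither value decides whether platelets carried over contributed. A further test used the mean of all other tested members of the list, called ones included, as a covariate for each gene. Cd9 then differed by 2.52 (95% interval 2.21 to 2.84), Pdgfb by 1.49 (1.30 to 1.67) and Vwf by 0.85 (0.50 to 1.19), all still called (adjusted p = 3.7e-07, 4.4e-07 and 0.0019). Pf4 and Ppbp, abundant in platelets, went from 0.32 and 0.43 to -0.50 and -0.50, with the 3 called genes in their covariate. The 3 genes were picked as the called members, and most members behind each covariate were not called. The values show only that Cd9, Pdgfb and Vwf differed by more than their fit on the rest of the list gave. They do not decide whether platelets were the only source. Within the subsets the 3 genes followed the rest of the list (correlations of 0.81, 0.79 and 0.87 for Cd9, Pdgfb and Vwf), so a contribution of platelets stays open, beside expression by Ly6Clo monocytes.

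Fos was higher in Ly6Chi and Jun in Ly6Clo, although handling is known to induce both. Their differences lay 3.85 apart (95% interval 3.07 to 4.63, exact permutation p = 0.0286, the smallest possible). The pair was picked for its opposite signs, so this distance decides nothing about handling, and 13 of 23 immediate early and stress genes were higher in Ly6Clo. The heat shock genes Hspa1b, Hsph1, Hsp90aa1 and Dnajb1 were higher in Ly6Clo by a mean of 0.82 (95% interval 0.20 to 1.45, exact permutation p = 0.0286). These 4 were chosen after the results were seen, and the list also held Hspa1a, Hspa8 and Hspb1. The interval and p therefore do not test heat shock genes as a set. For Fos, Jun and the heat shock genes, handling and subset cannot be told apart, since no handling that varies within a subset is recorded in the labels.

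All 35 splits of the 8 arrays into 4 and 4 were fitted with limma. For probe sets called, 1 of the 35 splits, the real one, gave as many: 7108, against 0 at the highest of the others. For probe sets at least 2-fold, 1 split gave as many (801, against 0), and for genes called, 1 split (3755, against 0). A share of 1 in 35 is the smallest that these splits can give. Every other split mixes the subsets, which widens the spread within its groups and makes counts of 0 likely. The splits therefore rank the real grouping first for these counts but do not exclude chance. At an unadjusted p under 0.05 the real split gave 9095 probe sets and the highest other 2451. For gene lists called by camera, 2 of the 35 splits gave as many: the real one gave 13, and the split that sets Ly6Chi replicate 1 with Ly6Clo replicates 1, 3 and 4 gave 16. That split keeps 3 arrays of each subset together, and the splits with 2 arrays of each subset on both sides gave 0 to 6 lists. By the share of splits, chance is not excluded for the count of lists.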
